A study of Mus musculus with 6 samples.

How the data were processed

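RNA was measured in 6 libraries of a mouse macrophage cell line. Per the labels, cells were transfected with 10 pmol of siRNA per well by lipofection and harvested 48 h later, total RNA was extracted on columns, and sequencing libraries were made with a stranded mRNA kit. The sample titles name 3 libraries siCTL, which received a non-targeting siRNA, and 3 siTET3, which received a single siRNA against Tet3. The treatment field of the labels names siTET3 in all 6 samples, so the groups rest on the titles alone. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

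The authors deposited a table of 22027 genes, all typed as protein coding, with a signal value per gene and library. These values were gene counts that the authors had divided by 1 size factor per library. This was read from the deposited values themselves, since 100% of the values in each library were whole multiples of the value of 1 read, within a tolerance of 0.001 reads. The deposited table also holds the authors' log2 fold changes, which are siCTL over siTET3 and were turned here to siTET3 over siCTL, and the authors' p-values and adjusted p-values from DESeq2, the tool the table is named for. The sign of 14010 of 14047 deposited fold changes matched siCTL over siTET3 means. Per the submitters' processing notes, the genome build was GRCm38 (mm10), and the aligner and the counting program are not given in the sources used here. Because the counting is not stated to use strand, reads of overlapping and antisense genes cannot be told apart. The other sheets of the deposited workbook were not used here. One repeats the full table in another order, another repeats selected genes, and the last holds numbers with neither header nor gene names.

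Recovered reads numbered 32874749, 34252124 and 61709131 in siCTL replicates 1, 2 and 3 and 37289904, 46303121 and 29587171 in siTET3 replicates 1, 2 and 3. At these depths 1 read was worth between 0.634 and 1.27 normalised units, and the floor of 3 reads lay between 1.90 and 3.82 units. Of the 22027 genes, 7980 were at 0 in every library. No pair of replicates was alike within sampling noise, with a median chi-square per gene of at least 1.58, so every library counted as 1 replicate.

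Gene identifiers were matched without their version numbers to GENCODE release M21, which is on GRCm38. This placed 21886 identifiers, 18937 of them with the same version. Coordinates are 1-based and come from that annotation.

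The test written before the data were examined assumed raw counts first and named a limma test for normalised values. Since the deposited values were normalised, the test was limma 3.58.1 in R 4.3.3, with a trend of the variance, on log2(value + 1) with group as the only term. Genes with a mean under 10 normalised units were left out, which left 11591 genes. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes, and intervals cover 95%. Values are given as mean ± SD over 3 libraries per group. Tet3 and Tet2 were also tested by an exact two-sided permutation test over the 20 assignments of the libraries.

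A set of 31 gene lists with 858 member symbols, 854 of them found, was fixed at the same time. The lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists. Each was also tested with an estimated correlation and with fry, which tests whether a set's genes move, on balance, one way. The test with an estimated correlation was stricter even for some lists whose estimate lay below 0.01. Counts of called genes are given over all genes tested and adjusted over the list alone.

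Genes were named by a rule fixed in advance. It takes Tet1, Tet2 and Tet3, and the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap, whose mean reached 100 units in the higher group, and whose symbol is not that of a predicted gene, mitochondrial gene, small RNA or pseudogene. It also takes up to 4 members, in order of p, of each list described. Only 7 genes fell past the threshold, so all were named. Genes named outside the rule are said to be so.

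The main test was tried on simulated data in which known genes were changed. With 11529 genes and no added trend, it recovered 65.2% of genes changed 1.5-fold, 95.5% of those changed 2-fold and 100% of those changed 4-fold, and 5.98% of its calls were false. With a trend of base content like that of these libraries added, most strongly to siCTL replicate 2, the same test on 11556 genes recovered 6.06%, 58.2% and 81.8% of genes changed 1.5-fold, 2-fold and 4-fold, with 1.02% of calls false. After removal of the trend, on 11487 genes, it recovered 73.8%, 92.5% and 100%, with 2.24% of calls false. Apart from the known changes, the simulated libraries differed only by that trend and random spread, so its removal had to restore the calls. In the real data the log2 deviations of siCTL replicate 2 kept an SD of 0.657 after removal, against at most 0.326 in the others. These rates therefore do not describe the real libraries.

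Alternatives fixed in advance were limma without the variance trend, the authors' deposited comparison, scaling to library size alone, no filter on low values, a filter of CPM of at least 1 in at least 3 libraries, pseudocounts of 0.1 and 10, stricter thresholds, the replicate number as a block, and omission of each library in turn. Scaling by DESeq2-type size factors, also listed, is the deposited scaling itself and gave no separate fit. Alternatives chosen after seeing the data were DESeq2 1.42.0 and edgeR 4.0.16 quasi-likelihood on the recovered reads, edgeR without siCTL replicate 2, limma with estimated library weights, TMM scaling, and removal from each library of a smooth trend of log2 values against transcript base content and length (natural splines with 3 degrees of freedom), with and without siCTL replicate 2. The estimated library weights did not converge. On the recovered reads edgeR's quasi-likelihood test called 32 genes higher and 6 lower, and DESeq2 gave the deposited log2 fold changes back (Pearson r of 1 across 14047 genes). Transcript composition was known for 99.5% of the tested genes. Figures were drawn with matplotlib 3.10.9.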

Results

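The transcriptome of a mouse macrophage cell line was profiled by RNA sequencing 48 h after transfection with a control siRNA (siCTL, n = 3) or an siRNA against Tet3 (siTET3, n = 3). Tet3 encodes an enzyme that oxidises methylated cytosine in DNA. The comparison addressed the effect of TET3 expression on gene expression in macrophages. The libraries held between 29587171 and 61709131 reads on protein-coding genes, and 14047 genes had a read in at least 1 library. All values are read counts scaled by the authors' size factors, called normalised read counts here.

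Tet3 mRNA was not detectably lower in the libraries labelled siTET3. Tet3 (ENSMUSG00000034832.15, chromosome 6, from 83362373 to 83459084 on the minus strand, GRCm38) had a normalised read count of 2036 ± 130 (SD, n = 3) in siCTL and 1957 ± 21.2 (SD, n = 3) in siTET3, or 96.1% of the control mean. The fold of siTET3 over siCTL was 0.962, with a 95% interval from 0.834 to 1.11 and a limma adjusted p of 0.699. The exact permutation test gave p = 0.4, and the smallest p this design allows is 0.1. The log2 change was -0.06 and turned to 0.03 when libraries were scaled to their size alone, so no direction was drawn. The authors' deposited table lists an adjusted p of 0.729 for Tet3. Because the target does not separate the groups, the treated libraries are called the libraries labelled siTET3, and every direction below is that of the labels.

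Of the related genes, Tet2 had 1388 ± 157 normalised reads in siCTL and 1777 ± 141 in the libraries labelled siTET3 (SD, n = 3), a log2 change of 0.36 that did not pass (limma adjusted p = 0.335). Its exact permutation p was 0.1, the smallest this design allows. The log2 change of Tet2 was 0.26 without siCTL replicate 2 and 0.15 with the base-content trend also removed (limma adjusted p = 0.126 and 0.209). Tet1 was at 0 in 5 libraries and at 1.63 in siTET3 replicate 2, below the floor of 3 reads. The list of TET and DNA methylation genes had 24 measured members, none of them called by limma with all libraries. Limma called 1 of them higher without siCTL replicate 2, Ogt, named after its values were seen (limma adjusted p = 0.0220), and the list's median was 0.02. With all libraries the median log2 change of the list was -0.03 although camera's direction was up, and it was not called (camera adjusted p = 0.932).

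Interferon-stimulated genes were higher in the libraries labelled siTET3. Rtp4 rose 5.19-fold, from 345 ± 10.0 to 1793 ± 87.6 normalised reads (SD, n = 3, limma adjusted p = 0.000659). Ifit1 and Ifit3, which encode antiviral proteins, rose 6.12-fold and 6.61-fold, and Oasl2, an oligoadenylate synthetase-like gene, rose 8.70-fold from a low level of 26.8 ± 11.5 normalised reads (SD, n = 3), with limma adjusted p-values of 0.00691, 0.00691 and 0.0238. Isg15, which encodes a ubiquitin-like modifier, rose 3.26-fold, and Usp18, which encodes the protease that removes that modifier, rose 3.51-fold. Of 38 measured members of the interferon list, 21 rose and none fell by limma, 17 did not pass, and 37 had a positive log2 change.

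The interferon list accounted for 21 of the 34 genes called higher. Its median log2 change was 1.18, and 35 of its genes passed when adjusted over the list alone. The list was called by camera (adjusted p = 5.7e-42), and the call held with an estimated correlation (adjusted p = 0.0197 with an estimated correlation). Among its members, Ifi44 rose from 2078 ± 295 to 7353 ± 363 normalised reads, Usp18 from 549 ± 10.7 to 1930 ± 111, Isg15 from 409 ± 51.6 to 1331 ± 40.9, and Xaf1, a gene linked to apoptosis, from 335 ± 3.90 to 899 ± 10.3 (SD, n = 3). Rsad2, which encodes the antiviral enzyme viperin, changed by 2.17 on the log2 scale, Zbp1, a sensor of Z-form nucleic acid, by 1.92, and Trim30a by 1.53. The limma adjusted p-values of these 7 genes ran from 0.00181 to 0.0179. The list count moved with single libraries. It was 16 without siCTL replicate 1, 36 without siCTL replicate 2, 7 without siCTL replicate 3, and 2 without each of siTET3 replicates 1, 2 and 3. The median log2 change stayed between 1.12 and 1.25 in those fits and camera called the list in all 6, while its adjusted p with an estimated correlation ran from 0.0332 to 0.141 and was under 0.05 only without siTET3 replicate 2.

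**Figure D1:**
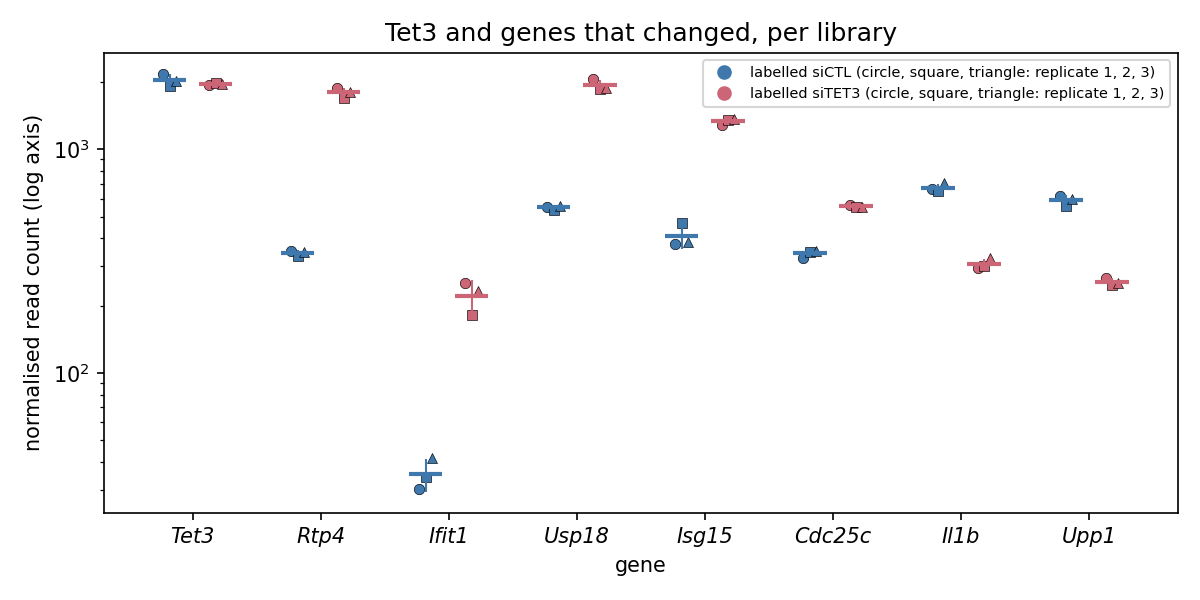
Normalised read counts, on a log axis, of Tet3 and of 7 genes past the threshold in the 3 libraries labelled siCTL and the 3 labelled siTET3, with horizontal bars at the group means and vertical bars of 1 SD. The groups overlap for Tet3 (2036 and 1957 on average) and do not overlap for the other genes, such as Rtp4 (345 and 1793) or Il1b (673 and 307).

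Across all 11591 genes tested, 34 were higher and 7 lower in the libraries labelled siTET3 (limma, adjusted p under 0.05). The groups did not overlap for any of the 41, nor for 3655 of the genes tested, or 31.5%, where chance gives 10%. Genes are not independent, and base content differed between the labelled groups, so this share does not measure how many genes respond. Outside the interferon list, the largest rises by the rule were those of Ugt1a1, a glucuronosyltransferase gene of bilirubin clearance, and H2-T24, a non-classical class I histocompatibility gene. Ugt1a1 went from 4.92 ± 1.29 to 413 ± 145 normalised reads and H2-T24 from 681 ± 109 to 2926 ± 186 (SD, n = 3), with limma adjusted p-values of 0.00321 and 0.00435. Ugt1a1 shares most of its exons with the other Ugt1a genes, and the total of all 9, Ugt1a1 included, differed by a fold of 1.07, so its count is uncertain. The number of calls depended on every library. Without siCTL replicates 1, 2 and 3 in turn, 22, 197 and 9 genes were higher and 2, 123 and 0 lower. Without siTET3 replicates 1, 2 and 3 in turn, 3, 2 and 2 genes were higher and none was lower. In limma, the only tool run without those libraries or siCTL replicate 3, 718, 694 and 663 genes had an unadjusted p under 0.05, and 1328 without siCTL replicate 3. Rtp4 and Usp18 passed in all 6 of these fits, with highest adjusted p-values of 0.0283 and 0.0494. The authors' deposited table lists 180 genes higher and 162 lower at the same threshold, which include all 41.

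Genes of mitosis and the G2/M phase were higher as a group in the libraries labelled siTET3. Cdc25c, a phosphatase that starts mitosis, rose from 342 ± 12.9 to 554 ± 8.79 normalised reads (SD, n = 3), a log2 change of 0.70 with a limma adjusted p of 0.0437. It was the only one of 42 measured members to pass limma over all genes tested, while 28 passed when adjusted over the list alone and 40 had a positive log2 change. Ccna2, which encodes cyclin A2, had 3705 ± 337 normalised reads in siCTL and 6314 ± 345 in the libraries labelled siTET3 (SD, n = 3). Its limma adjusted p was 0.0502 over all genes, and those of Plk1, a mitotic kinase, and Nusap1, a spindle protein, were 0.0573 and 0.0590. All 3 pass in the authors' deposited DESeq2 comparison (adjusted p = 7.8e-09, 4.1e-08 and 2.1e-07).

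The median log2 change of the mitosis list was 0.46, and camera called it (adjusted p = 3.3e-19), also with an estimated correlation (adjusted p = 0.0338 with an estimated correlation). Without siCTL replicate 2, 28 of its genes passed over all genes tested, and without any other single library none did (limma, the only tool run in those fits). With each library left out in turn camera called the list in all 6 fits, at adjusted p-values of 0.141, 0.0977, 0.129, 0.0808, 0.0369 and 0.116 with an estimated correlation, in the order siCTL replicates 1 to 3 and siTET3 replicates 1 to 3. The list of DNA replication and S phase genes was not called (camera adjusted p = 0.991), with 21 of 45 members positive and a median log2 change of -0.02. The difference between both cell cycle lists was not tested.

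The 7 genes that fell in the libraries labelled siTET3 were Upp1, Il1b, Pdpn, Lcn2, Socs3, Furin and Il4ra. Il1b, which encodes the inflammatory cytokine interleukin-1 beta, fell from 673 ± 26.8 to 307 ± 15.4 normalised reads (SD, n = 3, limma adjusted p = 0.00783), and its log2 change was -1.13. Upp1, a uridine phosphorylase gene, fell from 593 ± 31.6 to 255 ± 9.55 (SD, n = 3, limma adjusted p = 0.00691). Socs3, an inhibitor of cytokine signalling, fell from 8260 ± 388 to 4841 ± 79.5, and Lcn2, which encodes an iron-siderophore binding protein, from 19333 ± 1533 to 10992 ± 675 (SD, n = 3). The log2 changes of Pdpn, Furin and Il4ra were -0.96, -0.73 and -0.69, and the limma adjusted p-values of all 7 lay between 0.00691 and 0.0445. Without siCTL replicate 1 the count of 7 was 2, without siCTL replicate 2 it was 123, and without siCTL replicate 3 or any 1 siTET3 library it was 0. All 7 kept a negative log2 change in each of these fits.

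Among 26 measured inflammatory cytokines and chemokines, Il1b fell, Ccl22 rose and the rest did not pass limma over all genes tested. Ccl22, a chemokine that attracts T cells through its receptor CCR4, rose from 97.6 ± 9.01 to 223 ± 17.2 normalised reads (SD, n = 3, limma adjusted p = 0.0306). Ccl5 and Ccl7 had log2 changes of 0.77 and -0.86 with limma adjusted p-values of 0.156 and 0.167, against 0.00286 and 0.00231 in the authors' deposited DESeq2 comparison. Adjusted over the list alone, 2 were higher and 7 lower. The list was called lower by camera (adjusted p = 0.0196), a call lost with an estimated correlation (adjusted p = 0.40 with an estimated correlation). It was also lost without siCTL replicate 1 (camera adjusted p = 0.167) and without siCTL replicate 3 (camera adjusted p = 0.0887), while without siCTL replicate 2 it was 1.2e-05 (adjusted p = 0.0977 with an estimated correlation), with 2 genes higher and 6 lower over all genes tested.

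Markers of alternative macrophage activation and genes of the TGF-beta pathway were also called lower as lists. Of 11 measured alternative activation genes, Il4ra, the receptor chain for interleukin-4, fell and 9 had a negative log2 change. Cish, a cytokine-inducible inhibitor of signalling, had 160 ± 9.42 normalised reads in siCTL and 37.8 ± 17.2 in the libraries labelled siTET3 (SD, n = 3), with a limma adjusted p of 0.0694 and an adjusted p of 6.0e-06 in the authors' deposited DESeq2 comparison. Arg1 and Clec10a had log2 changes of -0.66 and -0.47 and passed in neither limma over all genes tested nor the deposited comparison, and that of Clec10a was -0.29 without siCTL replicate 2. Adjusted over the list alone, 3 genes were lower, and without siCTL replicate 2 limma called 2 over all genes tested, Cish among them (limma adjusted p = 0.0261). The camera adjusted p was 0.0024 (adjusted p = 0.28 with an estimated correlation). Of 23 measured TGF-beta genes, Furin fell, and 3 were lower when adjusted over the list alone and also over all genes tested without siCTL replicate 2. Id1, a transcriptional inhibitor, had a log2 change of -1.69 and Smad6 of -0.69, neither past limma's threshold over all genes, while Id1 passes in the authors' deposited DESeq2 comparison (adjusted p = 0.00333). The TGF-beta list had a camera adjusted p of 0.0475 (adjusted p = 0.31 with an estimated correlation), which became 0.131 without siCTL replicate 1, 0.0826 without siCTL replicate 3, 0.0609 without siTET3 replicate 2 and 0.0513 with scaling to library size alone.

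Genes of protein synthesis, energy metabolism and stress were called lower as lists by camera, by small amounts. Limma called none of their single genes over all genes tested with all libraries. At the preset correlation, camera called from 2 to 10 lists in each other split of the 6 libraries into groups of 3. Such a call alone therefore does not mark a difference between the labelled groups. Limma without siCTL replicate 2 called 2 ribosomal genes and 2 oxidative phosphorylation genes lower, the latter Ndufa13 and Ndufa2 (limma adjusted p = 0.0333 and 0.0424), and no glycolysis gene. With the base-content trend also removed, Ndufa2 passed and Ndufa13 did not (limma adjusted p = 0.0329 and 0.121). In that fit 4 ribosomal genes, 1 oxidative phosphorylation gene and 1 glycolysis gene were called lower. In the authors' deposited DESeq2 comparison, Rpsa and Rps19 of the ribosomal list pass (adjusted p = 0.0216 and 0.0329). Of 77 cytosolic ribosomal protein genes, 7 had a positive log2 change, and the median was -0.27 (camera adjusted p = 1.8e-09, and adjusted p = 0.25 with an estimated correlation), or -0.12 with the base-content trend removed. Rpsa had 105026 ± 10724 normalised reads in siCTL and 79742 ± 2702 in the libraries labelled siTET3, and Rps19 24064 ± 1781 and 19222 ± 688 (SD, n = 3). Rps16 and Rps9 had log2 changes of -0.43 and -0.39. Of 18 glycolysis genes, 1 had a positive log2 change and the median was -0.23 (camera adjusted p = 0.0018, and adjusted p = 0.40 with an estimated correlation), or -0.14 without siCTL replicate 2 and -0.10 with the base-content trend removed. Among them Aldoc, Hk1, Slc2a1 and Aldoa had log2 changes of -0.22, -0.66, -0.21 and -0.25, and that of Hk1 was -0.34 without siCTL replicate 2. Of 74 oxidative phosphorylation genes, 26 were positive and the median was -0.13 (camera adjusted p = 0.0186, and adjusted p = 0.31 with an estimated correlation), with log2 changes of -0.53 for Ndufa13, -0.37 for Atp5d, -0.30 for Ndufv1 and -0.50 for Ndufa2. Without siCTL replicate 2 that median was -0.07 and Ndufa2 was at -0.29. The oxidative phosphorylation call was lost without siCTL replicate 1 (camera adjusted p = 0.153) and with the base-content trend removed (camera adjusted p = 0.0569).

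The remaining lists called lower were those of cholesterol synthesis and uptake, the integrated stress response, chaperones of the endoplasmic reticulum and p53 targets. In the cholesterol list of 24 genes, Mvd, an enzyme of the mevalonate pathway, was lower when adjusted over the list alone, with 6204 ± 158 normalised reads in siCTL and 4545 ± 146 in the libraries labelled siTET3 (SD, n = 3). Limma called no gene of these 4 lists over all genes tested with all libraries. It called 2 cholesterol genes lower without siCTL replicate 2, Mvd and Pmvk (limma adjusted p = 0.0111 and 0.0299), and 2 p53 targets, Ddit4 and Bbc3 (limma adjusted p = 0.0384 and 0.0370). With the base-content trend also removed, Mvd passed and Pmvk, Ddit4 and Bbc3 did not (limma adjusted p = 0.0122, 0.288, 0.0599 and 0.106). In that fit 4 cholesterol genes and 1 p53 target were called lower. In the authors' deposited DESeq2 comparison of all libraries Mvd, Mvk, Aldh1l2, Ddit4 and Bbc3 pass (adjusted p = 2.0e-07, 0.0401, 0.00513, 0.00073 and 0.00266). Mvk and Pmvk had log2 changes of -0.46 and -0.82, and that of Pmvk was -0.48 without siCTL replicate 2. The camera adjusted p of the cholesterol list was 0.0024 (adjusted p = 0.31 with an estimated correlation) and 0.129 without siCTL replicate 1. The stress response list of 27 genes had a median of -0.20 (camera adjusted p = 0.0024, and adjusted p = 0.31 with an estimated correlation), with Aldh1l2, Wars, Nupr1 and Phgdh at -0.25, -0.28, -0.66 and -0.35. Without siCTL replicate 2 its median was -0.11 and Nupr1 and Phgdh were at -0.37 and -0.22, and with the base-content trend removed the median was -0.03. The chaperone list of 18 genes had a median of -0.22 (camera adjusted p = 0.0143, and adjusted p = 0.31 with an estimated correlation), and Hspa5, the main chaperone of that compartment, was at -0.24, Pdia4 at -0.47, Herpud1 at -0.26 and Pdia6 at -0.32. Without siCTL replicate 2 the chaperone median was -0.12, with Pdia4 at -0.31 and Pdia6 at -0.18. The p53 list of 27 genes had a median of -0.19 (camera adjusted p = 0.0193, and adjusted p = 0.28 with an estimated correlation), lost without siCTL replicate 1 (camera adjusted p = 0.201). In it Ddit4 and Bbc3 were lower when adjusted over the list alone, at log2 changes of -0.51 and -0.73, and Phlda3 and Gdf15 were at -0.46 and -0.96.

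**Figure D2:**
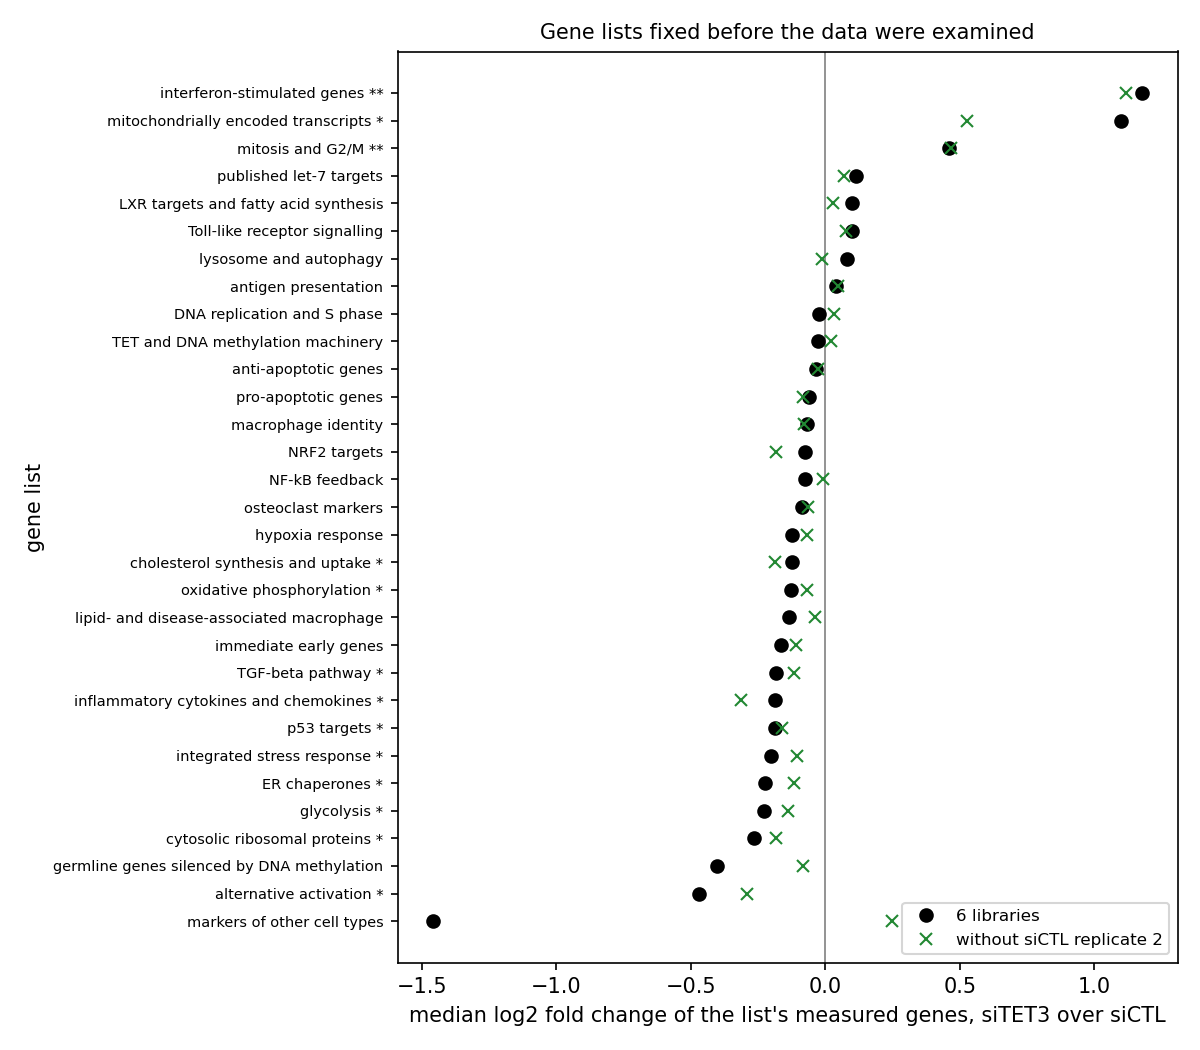
Median log2 fold change (siTET3 over siCTL labels) of the measured genes of each of the 31 lists, with all 6 libraries (circles) and without siCTL replicate 2 (crosses). A star marks a camera adjusted p under 0.05 and a double star a call that also held with an estimated correlation, which the interferon and mitosis lists have at medians of 1.18 and 0.46.

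One control library stood apart from the other 5. Mitochondrially encoded transcripts made up 0.551% of the reads of siCTL replicate 2 and between 2.53% and 3.03% of those of every other library. The share was 2.53% and 2.61% in siCTL replicates 1 and 3, and 2.95%, 2.79% and 3.03% in siTET3 replicates 1, 2 and 3. The first principal component held 66.2% of the variance and set that library at 83.3, with the others between -22.0 and -4.21. All 13 mitochondrially encoded genes had a positive log2 change, with a median of 1.10 and a camera adjusted p of 8.8e-05 (adjusted p = 0.40 with an estimated correlation). The values of mt-Nd2 were 25258 ± 12805 and 48007 ± 4477 normalised reads (SD, n = 3), and mt-Nd6, mt-Nd4l and mt-Nd3 had log2 changes of 0.66, 1.61 and 3.05. The log2 change of mt-Nd2 was 1.10, or 0.55 without siCTL replicate 2, and turned to -0.79 with the base-content trend removed. None passed limma over all genes tested or over the list alone, while mt-Nd6 passes in the authors' deposited DESeq2 comparison (adjusted p = 0.0325). Without siCTL replicate 2 the list median was 0.53 and 1 gene passed. In that fit camera still called the list higher (camera adjusted p = 1.2e-05, and adjusted p = 0.20 with an estimated correlation). With the base-content trend removed the median was 0.12, camera's direction was down and the call was lost (camera adjusted p = 0.670). With siCTL replicate 2 also left out, the median was -0.04 (camera adjusted p = 0.896).

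**Figure D3:**
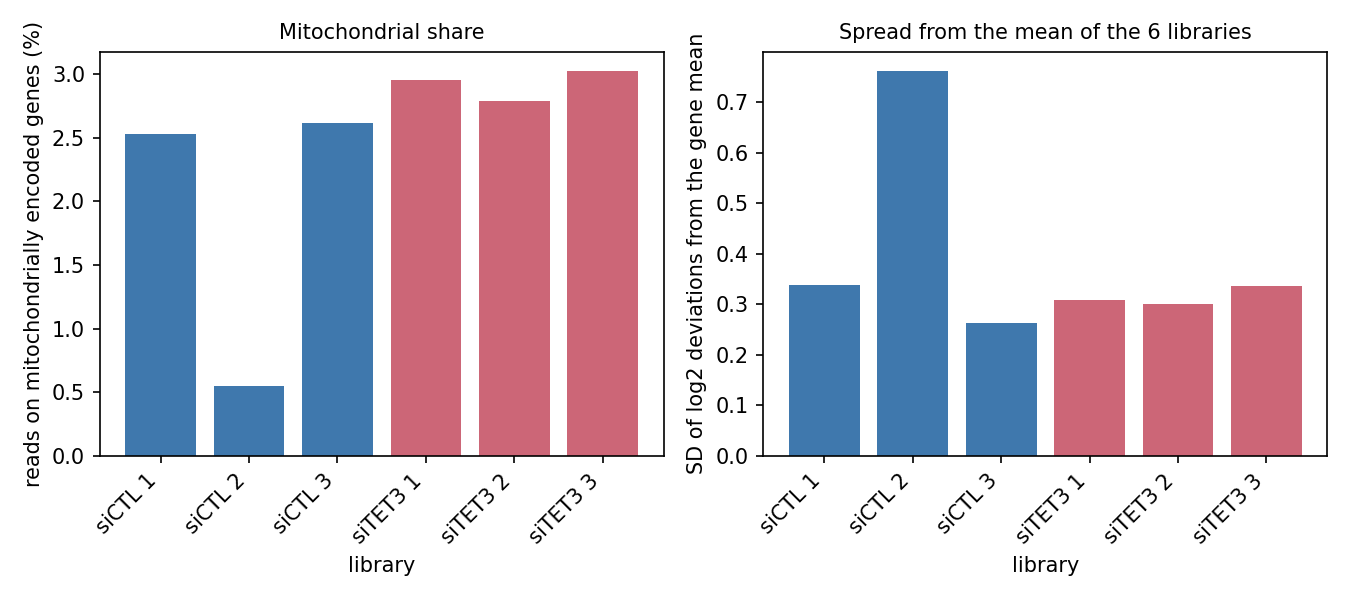
Share of reads on mitochondrially encoded genes, in percent, and standard deviation over 11529 genes of each library's log2 deviations from the mean of the 6 libraries. Bars are single libraries, and siCTL replicate 2 has 0.551% of its reads on these genes and a standard deviation of 0.762, against at most 0.339 in the others.

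The markers of other cell types moved with the same library. Of 32 such markers, 5 were measured above the filter, with a median log2 change of -1.46 with all libraries and 0.25 without siCTL replicate 2, and the list was not called (camera adjusted p = 0.299). Fold changes followed base content across genes, which are not independent replicates, with a Spearman correlation with GC content of -0.57 with all libraries and -0.49 without siCTL replicate 2. Each library's log2 deviations correlated with GC content at -0.17, 0.50 and 0.30 (Spearman) in siCTL replicates 1, 2 and 3. In siTET3 replicates 1, 2 and 3 the values were -0.45, -0.43 and -0.56, so base content separated the labelled groups.

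Several lists were not called by camera and held single genes that passed limma when adjusted over the list alone. That adjustment does not cover the 31 lists, and 1530 of the 11591 genes tested had an unadjusted limma p under 0.05. Single passes in a list are therefore weak evidence about the list. With siCTL replicate 2 left out, limma called over all genes tested 2 osteoclast markers, 2 lysosome genes and 2 hypoxia genes lower, 1 let-7 target higher, and 1 LXR list gene higher and 1 lower. Of these lists, fry called the osteoclast markers lower and the let-7 targets higher (fry adjusted p = 0.0213 and 0.0311). In the authors' deposited DESeq2 comparison Mmp9, Acp5, Ocstamp, Sqstm1, Gaa, Wipi1, Abca1, Hmga2 and Ddit4 pass over all genes, with adjusted p-values of at most 0.00816. Among 15 osteoclast markers, 1 was higher and 5 lower in that sense (camera adjusted p = 0.0789). Mmp9, a matrix metalloproteinase, had 14513 ± 1037 and 9008 ± 188 normalised reads (SD, n = 3, limma adjusted p = 0.0502), Acp5, the tartrate-resistant acid phosphatase, 28088 ± 2125 and 19445 ± 870, and Ocstamp and Itgb3 had log2 changes of -0.50 and -0.70. The osteoclast list was called lower without siCTL replicate 2 (camera adjusted p = 0.0389), a call lost with an estimated correlation (adjusted p = 0.247 with an estimated correlation). In the lysosome and autophagy list 3 of 31 genes were lower, Sqstm1, Gaa and Wipi1, at log2 changes of -0.58, -0.39 and -0.47 (camera adjusted p = 0.631), next to Gabarapl1 at -0.28. Abca1, the cholesterol exporter, was higher in the list of LXR targets and fatty acid synthesis, with 861 ± 89.4 and 1484 ± 61.6 normalised reads (SD, n = 3, limma adjusted p = 0.0502, camera adjusted p = 0.299), and Abcg1, Fasn and Nr1h2 were at 0.44, -0.32 and -0.26, the last turning to 0.03 with the base-content trend removed. Hmga2 was higher among published let-7 targets, at 0.53 (camera adjusted p = 0.149), with Cdc25a and Tgfbr1 at 0.19 and 0.68, and Tgfbr1 at 0.24 without siCTL replicate 2. Ddit4 was also lower in the hypoxia list (camera adjusted p = 0.312), in which Kdm3a, Vegfa and Ndrg1 were at 0.41, -0.51 and -0.35, or at 0.22, -0.25 and -0.19 without siCTL replicate 2.

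With all libraries no gene passed limma, over all genes or over the list alone, in the other lists, and neither camera nor fry called any of them. Omission of siCTL replicate 2 led limma to call 3 NRF2 targets, 1 pro-apoptotic gene and 1 immediate early gene lower, and 1 gene each higher of NF-kB feedback, macrophage identity and antigen presentation. The camera adjusted p was 0.504 for NF-kB feedback genes, 0.0826 for Toll-like receptor signalling, 0.0530 for immediate early genes, 0.0789 for NRF2 targets, 0.128 for genes of lipid- and disease-associated macrophages, 0.714 for macrophage identity genes and 0.450 for antigen presentation. It was 0.251 for pro-apoptotic genes, 0.759 for anti-apoptotic genes, whose median log2 change was -0.03 and mean 0.01, and 0.287 for germline genes silenced by DNA methylation, of which 3 of 20 were measured. Toll-like receptor signalling was called higher without siCTL replicate 3 (camera adjusted p = 0.0303), NRF2 targets lower without siCTL replicate 2 (camera adjusted p = 1.1e-05), and immediate early genes lower without siCTL replicate 3 or siTET3 replicate 1 (camera adjusted p = 0.0248 and 0.0335). All 4 of these calls were lost with an estimated correlation (adjusted p = 0.408, 0.0977, 0.407 and 0.373 with an estimated correlation, in that order). With the base-content trend removed, hypoxia genes and NRF2 targets were called lower and LXR targets higher (camera adjusted p = 0.0302, 0.0271 and 0.0302). With siCTL replicate 2 also left out, the hypoxia and LXR calls were lost (camera adjusted p = 0.0512 and 0.410), the NRF2 call was kept only at the preset correlation (camera adjusted p = 6.4e-07, and adjusted p = 0.0747 with an estimated correlation), and antigen presentation was called higher (camera adjusted p = 0.0226, and adjusted p = 0.227 with an estimated correlation) with 4 genes higher and 1 lower.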

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

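The alternatives on recovered reads, library weights, TMM and base content were chosen only after the result was seen. Beside 34 genes higher and 7 lower, the authors' deposited comparison listed 180 and 162, DESeq2 on the recovered reads 182 and 156, edgeR without siCTL replicate 2 372 and 382, and limma with estimated library weights, which did not converge, 3289 and 3304. With the base-content trend removed the counts were 58 and 15, and also without siCTL replicate 2 they were 288 and 188. At an adjusted p under 0.01 they were 17 and 2, which a stricter threshold makes fewer by construction. The count of lower genes was 11 without a trend of the variance, 2 with scaling to library size alone, 4 without a filter and 2 at a fold of at least 2. Scaling to library size moved the share of higher genes among the calls from 82.9% to 93.1%. Omission of 1 library gave from 2 to 197 higher and from 0 to 123 lower genes. The 41 genes were all called in the deposited comparison, with TMM, and without siCTL replicate 2, and 34 of them with the trend removed. The number of libraries alone does not set the count, since omission of siCTL replicate 2 raised it and omission of any other library lowered it. Apart from the stricter threshold, the causes of these differences were not tested.

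The Tet3 log2 fold change reversed to 0.0286 with scaling to library size alone, to 0.25 with the trend removed and to 0.00555 with that and without siCTL replicate 2, at adjusted p-values from 0.575 to 0.981. Its adjusted p over all settings ran from 0.195 to 0.981. With the trend removed Nr1h2 reversed to 0.0259 and mt-Nd2 to -0.789, and mt-Nd2 to -0.0414 also without siCTL replicate 2. No other named gene reversed in the settings it was run in.

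Lists called lower numbered 10, and 0 with an estimated correlation, 5 with fry, and from 5 to 12 with 1 library left out, where lists called higher numbered 3 or 4. Those 5 of fry were TGF-beta genes, p53 targets, ribosomal proteins, alternative activation genes and osteoclast markers (fry adjusted p = 0.0081, 0.0128, 0.0128, 0.0193 and 0.0213). Loss of a call with an estimated correlation does not by itself show that a list's genes are correlated. The TGF-beta and p53 lists had estimates of -0.03 and -0.02, below the preset 0.01, yet their camera adjusted p rose to 0.31 and 0.28. With the replicate block, 1 gene was higher and 0 lower at 1175 genes with an unadjusted p under 0.05, and 3 lists were higher and 11 lower. Same-numbered libraries had deviations that correlated at 0.03, -0.06 and -0.10, and no library correlated best with its own number. The numbers were therefore not taken to pair the libraries.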

Other observations

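The tests of trends, labels, Tet3 level, depth, shared reads, response to siRNA, siRNA seed words and other splits below were chosen only after the result was seen, as was the use of the fit without siCTL replicate 2 as a test of the interferon genes, though that fit was planned, as were the limma values. The bounds of the test on fibroblast transcripts were set before its result. Called genes outside the lists, named after their values were seen, included further genes known to respond to interferon. Slfn4 rose from 5131 ± 374 to 10141 ± 315 normalised reads, Slfn5 from 1398 ± 112 to 2616 ± 33.6, Ifi27l2a from 627 ± 63.1 to 1338 ± 128, and Dtx3l from 950 ± 49.8 to 1633 ± 111 (SD, n = 3), with limma adjusted p-values from 0.0126 to 0.0360. Prr11, Sass6 and Pif1, which act in cell division, centriole assembly and genome maintenance, rose by 0.96, 0.77 and 0.99 on the log2 scale (limma adjusted p = 0.00778, 0.0360 and 0.0251). Reads on 21 type I, II and III interferon genes numbered 0 in siCTL replicates 1, 2 and 3 and 0, 6 and 3 in siTET3 replicates 1, 2 and 3, all on Ifnb1 and Ifna2.

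The rise of interferon-stimulated genes was set against technical explanations. A base-content and length trend was not the whole cause, since the list's median log2 change with the trend removed was 1.09, nor was siCTL replicate 2 alone, since 36 list genes passed without it. The nearest libraries of both groups lay 1.19 apart in mean log2 of the list, so each library lay with its own group. That gap argues against a single wrong or swapped library label only if the interferon genes follow the siRNA received, which was not tested. An exchange of the labels of both whole groups is not excluded by that gap. A Tet3 mRNA level at harvest under 0.7 of control was excluded by the lower bound of 0.834 on its fold. A response to the transfected siRNA itself stays open and cannot be told apart from an effect of TET3, because the design holds 1 siRNA against Tet3. TET3 protein, and Tet3 mRNA before 48 h, were not analysed here, and lower TET3 at those points also stays open.

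The distance of siCTL replicate 2 from the other 5 libraries was not explained by depth, since its 34.3 M reads lie inside the range of the others. A base-content and length trend explained 25.7% of the variance of its log2 deviations, and their SD was 0.657 with that trend removed, against at most 0.326 in the others. RNA from fibroblasts may be present, since 11 of 20 listed fibroblast transcripts were high in that library alone, where 12 were needed and 4 or fewer would have excluded it. The most abundant of the list were Fn1 at 707, Mgp at 307, Sparc at 257 and Bgn at 180 normalised reads, while Thy1, Postn and Fbn1 were at 0 in it, Lox and Acta2 were found in all 6 libraries, and of the wider list of other cell types Col1a2 was at 286, Col3a1 at 144 and Pdgfra at 109, and Col1a1, Dcn and Lum at 0. That leaves fibroblasts open. No other biological explanation was tested, and the label gives that library the same treatment as the other controls.

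Large rises of genes that share exons or overlap with others may come from how reads were assigned. The Ugt1a family total was 4572 ± 516 in siCTL and 4895 ± 200 in the libraries labelled siTET3 (SD, n = 3), a fold of 1.07, against a rise of 408 in Ugt1a1, and Ugt1a2 read 0, 0 and 318 in siCTL and 441, 0 and 0 in siTET3. Gm20431, named after its values were seen, was at 0 in siCTL and at 93.8, 436 and 191 in siTET3 replicates 1, 2 and 3. Its total with the overlapping Ube2v1 and Tmem189 had a fold of 0.934. In both cases reads shared between the genes and a change of the named transcript cannot be told apart, because the totals vary by as much as the rise or move against it.

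A search of 3' untranslated regions for a 7-base word that goes with lower transcripts, as the seed of an siRNA would, gave a lowest z of -3.97 without siCTL replicate 2, between the median of -3.88 and the 5th percentile of -4.41 of 100 shuffles. With all libraries it was -6.42, beyond the 5th percentile of -4.53, so the outcome rests on that library.

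The 6 libraries make 10 splits into groups of 3, too few for a share under 0.05. For the count of genes called, the real split gave 41 and the highest other 1, so 1 of the 10 splits reached it, and for the gene lists called, the real split gave 13 and the highest other 10, with 1 of 10 splits reaching it. Each other split called at least 2 lists at the preset correlation. With an estimated correlation the real split called 2 lists and the others 0.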
